A study of Mus musculus with 3 samples.

How the data were processed

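DNA methylation was measured in 3 libraries of ID8, an ovarian cancer line of C57BL/6 mice that the labels describe as female ovarian surface epithelial cells, grown without treatment. The assay was digital restriction enzyme analysis of methylation (DREAM). In DREAM, genomic DNA is cut at CCCGGG sequences first by SmaI, which is blocked by CpG methylation, and then by XmaI, which is not. A fragment end reading GGG therefore marks an unmethylated site and an end reading CCGGG a methylated one. Per the labels' protocols, methylation standards were spiked into the DNA and barcoded pools were sequenced on an Illumina HiSeq2500. Bowtie2 and SAMtools are named in the submitters' processing notes, which list the builds mm9 and rn4. The site identifiers in the deposited files name mm9, and coordinates are given as in those files; tool versions and the convention of the site position are not given in the sources used here.

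Each library's table lists the same 173449 CCCGGG sites with the counts of methylated, unmethylated and total reads that the authors deposited, which are not normalized. The authors also deposited 2 percent columns. The raw percent equals methylated reads over total reads, and the adjusted percent equals the same share after the odds of methylated to unmethylated reads are multiplied by 1 factor per library. From the values this library factor was 2.02, 1.81 and 1.73 in replicates 1, 2 and 3; how the authors obtained it is not given in the sources used here. A table of the whole series holds the counts of the 3 libraries summed, for the 46411 sites with at least 10 summed reads, with percent columns made in the same way and a factor of 1.89.

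The methylation level of a site was computed as the methylated share of the deposited counts in each library, and is reported as the mean and SD of the 3 libraries. Sites with at least 10 reads in every library were kept and are called covered sites. Sites were classed by their mean level as low (under 10%), partial (10% to under 70%) or high (70% or more). Total reads were 7689526, 9190335 and 10361138 in replicates 1, 2 and 3, and the median covered site had 158, 186 and 211 reads. Whether copies of the same molecule were collapsed is not given in the sources used here, so intervals (exact Clopper-Pearson, 95%) and limits from a count of 0 (3 reads) cover counting error only. The series describes the samples as independent, but separate cultures are not stated, so p-values over libraries measure only the spread between these samples, which may be technical.

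The plan written before the data were examined compared CpG islands and promoters with other sites, tested promoter methylation of fixed gene lists and named genes from them. The deposited tables carry no gene or CpG island annotation and no annotation on mm9 was used here, so those comparisons were not analysed, no gene is named, and the planned comparison of the X chromosome with the autosomes was made over all covered sites. In place of CpG islands, the spacing of the listed sites was used, a choice made after the tables were seen. A site with at least 2 other listed sites within 500 bp is called clustered and a site with none is called isolated. Clusters are runs of listed sites no more than 500 bp apart with at least 3 covered sites. The rule for named sites was the 5 called sites with the largest difference; clusters and windows are named by total reads, number of sites or level, by rules chosen after the tables were seen. The clusters, windows, neighbour distances and chromosome depths were likewise chosen as results after the tables were seen, as was the test of the partial class alone on X.

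Pairs of libraries were compared by Fisher's exact test per site (two-sided) with Benjamini-Hochberg adjustment over sites; a call needed an adjusted p under 0.05 and a difference of at least 20 percentage points. The excess over counting error was measured as the mean chi-square per degree of freedom over sites with expected counts of at least 5, which is 1 with counting error alone. The X chromosome was compared with the autosomes by Fisher's exact test over sites, and over clusters with 1 value each. Sites are not independent replicates, nearby sites were alike in methylation, and all X sites lie on 1 chromosome. The p-values over sites can therefore be far too small, also for this line, and are given as description only. Window means of isolated autosomal sites were compared with 100000 shuffles of the levels among windows of 5 Mb, after sites no more than 1 kb apart were averaged. Depth per chromosome was the median log2 ratio of a site's reads to the median of autosomal sites with the same methylation class and the same distances to both neighbouring sites, with a 95% interval from 2000 bootstrap draws of blocks of 1 Mb. On simulated counts with the depths and levels of replicates 1 and 2 and 200 of 24112 sites changed, the pairwise test recovered 33% of changes of 20 percentage points, 70.5% of changes of 30 points and 81% of changes of 40 points, with 1, 1 and 0 false calls. Alternatives were coverage minimums of 20 and 50 reads, 30 pooled reads, other class limits, the adjusted percent, other spacing limits, leaving out the 7 deepest sites and leaving out each replicate. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.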

Results

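The data describe the methylation of CCCGGG sites in untreated ID8 cells, in 1 group of 3 libraries with no control. Of 173449 listed sites, 91041, 94267 and 97281 had at least 1 read in replicates 1, 2 and 3, and 26133, 27749 and 28019 had at least 10. The 24112 sites with at least 10 reads in every library made up 13.9% of the listed sites and held 97.4%, 97.4% and 97.6% of the reads. At the 118 sites listed on chromosome Y no read was counted in any library, which allows at most 3.9e-05% of the reads of replicate 1, 3.26e-05% of replicate 2 and 2.9e-05% of replicate 3.

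The first question was how methylation was distributed in this line. Levels in ID8 gathered near 0 and near 100%. The mean level over covered sites was 43.3% ± 0.170 (SD, n = 3), and 45.3% ± 0.0287 of the sites were low, 15.9% ± 0.233 were partial and 38.8% ± 0.257 were high. Of the 24112 sites, 3646 had no methylated read and 2278 had no unmethylated read in any library. The low sites were read more deeply, with a median of 802 reads summed over the libraries, than the partial sites with 587 and the high sites with 338. The authors' adjusted percent put the mean at 46.5% ± 0.327 (SD, n = 3), with 42.8% of sites low, 14.9% partial and 42.3% high.

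The 3 libraries were then compared with each other. Levels differed little between them: the median absolute difference per site was 0.391 percentage points between replicates 1 and 2, 0.407 between 1 and 3, and 0.379 between 2 and 3. Across sites, which are not independent replicates, Pearson's r was 0.993, 0.994 and 0.994 for the same pairs, and 0.875, 0.882 and 0.881 over the partial sites alone. Of the low sites, 96.8% were low in each library, and 96.5% of the high sites were high in each, against 82.6% of the partial sites. The median SD between libraries was 0.134 percentage points at low sites, 3.17 at partial sites and 0.757 at high sites.

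Fisher's exact test with Benjamini-Hochberg adjustment called 1 site between replicates 1 and 2, 1 between 1 and 3, and 0 between 2 and 3. At an unadjusted p under 0.05 the pairs had 728, 723 and 685 of the 24112 sites, and without the minimum difference the adjusted counts were 10, 9 and 6. The site at position 66571739 of chromosome 14 (mm9) was methylated in 78 of 136 reads in replicate 1 (57.4%, exact Clopper-Pearson interval 48.6% to 65.8%). In replicate 2 it was methylated in 72 of 83 reads (86.7%, interval 77.5% to 93.2%) and in replicate 3 in 69 of 104 (66.3%, interval 56.4% to 75.3%), with an adjusted exact p of 0.020 between replicates 1 and 2. The site at position 134704424 of chromosome 4 was methylated in 28 of 155 reads (18.1%, interval 12% to 25%), 42 of 134 (31.3%, interval 23.6% to 39.9%) and 62 of 139 (44.6%, interval 36.2% to 53.3%) in the 3 libraries, with an adjusted exact p of 0.012 between replicates 1 and 3. Both calls involve replicate 1: without it 0 sites were called, against 1 without replicate 2 and 1 without replicate 3. The chi-square test in place of Fisher's test called 2 sites, and 0 sites once it was divided by the excess spread between libraries. That spread was 1.40, 1.37 and 1.30 times counting error for the 3 pairs. The numbers of reads per site also varied beyond counting error. Their mean chi-square per site was 8.25 and 9.90 between replicate 1 and replicates 2 and 3, and 1.79 between replicates 2 and 3. Each library was counted as 1 sample, but these values cannot tell separate cultures from repeated preparations of the same DNA.

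Methylation fell with the number of neighbouring CCCGGG sites up to 3 to 4 neighbours. Isolated sites averaged 60.9% ± 0.255 (SD, n = 3), sites with 1 neighbour within 500 bp averaged 44.3% ± 0.151, with 2 neighbours 30.9% ± 0.151, and with 3 to 4 neighbours 23.9% ± 0.138. The most crowded sites, with 5 or more neighbours, averaged 26.6% ± 0.0969, and 23.2% of them were high against 20.3% with 3 to 4 neighbours. Only 6.91% of the listed sites of that class were covered, against 26.6% with 3 to 4 neighbours. The SDs are over libraries and do not measure the spread over sites, so a rise in the densest class was not tested. High levels were found at 56.9% of the isolated sites and 23.8% of the clustered sites, and low levels at 27.3% and 62.3%. Of the 5924 covered isolated sites, the 1503 with no neighbour within 1 kb averaged 94.8% ± 0.334, and 96.1% of them were high. They were 1.36% of the 110705 such sites listed, with a median of 56 summed reads. Their level raises the mean of the isolated class, so its step to sites with 1 neighbour rests partly on them. Clustered sites lay 33.0 percentage points below isolated sites, as a signed difference of -33.0 ± 0.116 (SD, n = 3), in 3 of 3 libraries. The exact sign-flip test over 3 libraries gave p = 0.25 (two-sided), the smallest p that this number of libraries allows. The size of the difference depended on the definition. It was -20.5 points with at least 50 reads per library and -63.4 points with a spacing limit of 1 kb, and only 4.84% of the listed isolated sites were covered, with a median of 96 reads against 949.5 at clustered sites.

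Adjacent covered sites up to 1 kb apart were more alike in methylation than adjacent sites further apart. The pairs were not matched on the number of neighbouring sites, so distance and site density cannot be told apart. The assay reads fragment ends, so close adjacent sites can be ends of the same fragments. Coverage also fell with spacing, from 47.4% of listed sites with 1 neighbour within 500 bp to 1.36% with none within 1 kb. A limit of the assay on fragment length therefore cannot be told apart from the step at 1 kb either. Adjacent covered sites up to 100 bp apart differed by 17.4 percentage points on average (± 0.191, SD, n = 3). The difference was 16.7 ± 0.0730 at 100 to 250 bp, 24.3 ± 0.0610 at 250 to 500 bp and 25.9 ± 0.108 at 500 to 1000 bp. From 1 to 5 kb it was 47.0 ± 0.0728, close to the 48.2 ± 0.0307 of adjacent sites over 100 kb apart. A low site stood next to a high site in 5.96% of the 621 pairs up to 100 bp apart, in 12.4% of the 2368 pairs 500 to 1000 bp apart and in 36.2% of the 5088 pairs over 100 kb apart.

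**Figure D1:**
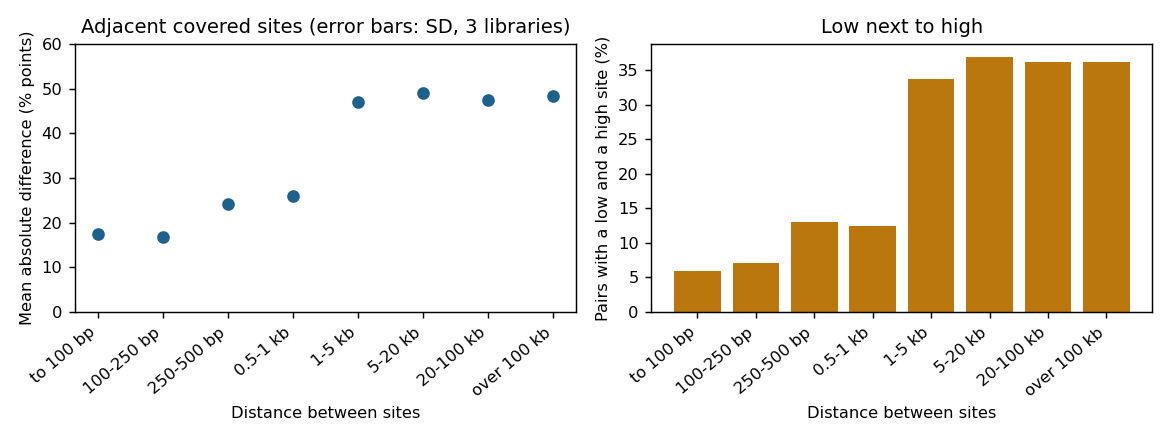
Left, mean absolute difference in methylation level (percentage points) between adjacent covered sites against their distance, with the SD of the 3 libraries as error bars, which are smaller than the points. Right, the percent of these pairs in which 1 site was low (under 10%) and the other high (70% or more); both measures step up beyond 1 kb, from 25.9 to 47.0 percentage points and from 12.4% to 33.6%.

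The 1744 clusters with at least 3 covered sites held 6255 sites. Every site was low in 813 clusters (46.6%) and high in 203 (11.6%), and 288 (16.5%) held both a low and a high site. These counts depend on the settings. A minimum of 50 reads left 117 clusters with every site high and 160 with both kinds of site, and a gap limit of 250 bp left 413 low, 100 high and 62 with both, against 492 with both at 1 kb.

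Among the clusters with every site high, the 10 with the most reads lay on 6 chromosomes. Chromosome 11, with 2139 of the 24112 covered sites, held 3 of them. A ranking by reads favours deeply read chromosomes, so these places do not show where such clusters gather. The deepest was on chromosome 19 from 25580404 to 25581452, where 4 sites averaged 93.0% ± 0.496 (SD, n = 3) over 17204 reads. A second cluster of chromosome 19, from 45305663 to 45306522, averaged 90.1% ± 0.355 over 6 sites. On chromosome 15, the 3 sites from 101062028 to 101062542 averaged 98.9% ± 0.0818, and those from 93425517 to 93426216 averaged 86.6% ± 0.277. The 7 sites on chromosome 4 from 154009761 to 154011203 averaged 98.3% ± 0.384, and the 7 on chromosome 3 from 94976346 to 94977511 averaged 98.6% ± 0.307. The 4 sites on chromosome 2 from 118502640 to 118503489 averaged 93.6% ± 0.287. On chromosome 11, the clusters starting at 118950404, 95866069 and 120132994 averaged 97.4% ± 0.147, 93.8% ± 0.818 and 96.7% ± 0.382.

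The deepest clusters with every site low were close to 0. The 9 sites on chromosome 5 from 143577870 to 143580189 averaged 0.134% ± 0.0501 (SD, n = 3) over 31817 reads, and no site there exceeded 0.376%. On chromosome 15, the clusters starting at 97661045, 59479782 and 12251413 averaged 0.291% ± 0.0723, 0.321% ± 0.396 and 0.0611% ± 0.0482. On chromosome 11, the 5 sites from 59918476 to 59919693 averaged 0.255% ± 0.111. Single libraries weigh on 2 of these values: the cluster at 59479782 was at 0.0926% without replicate 2 and 0.102% with a minimum of 50 reads, and that at 12251413 at 0.0336% without replicate 1. By the authors' adjusted percent the 5 clusters lay between 0.118% and 0.569%.

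Clusters with low and high sites changed level between adjacent sites, and in the 5 clusters with the most sites the SD between libraries was at most 4.32 percentage points at any site. On chromosome 2, the site at 153353912 was at 99.5% ± 0.107 (SD, n = 3) and the next covered site, at 153354380, at 3.82% ± 0.710; the remaining 7 sites of the cluster, up to 153355875, lay between 0% and 0.614%. On chromosome 4, the level went from 99.7% ± 0.102 at 114580495 to 0.148% ± 0.257 at 114581085. On chromosome 13, 8 sites from 55311687 to 55313064 lay between 90.9% and 100%, the site at 55313229 was at 21.9% ± 3.45 and the site at 55313342 at 0.345% ± 0.597. On chromosome 8, 8 sites from 91565089 to 91566857 lay between 42.3% and 99.0%, and the last sites, at 91567214 and 91567388, were at 2.0% ± 1.8 and 0%. These last sites held only 122 and 133 summed reads, and the site at 91566824, at 42.3%, only 129. With a minimum of 50 reads in every library all of these were lost, and the cluster mean went from 65.1% to 86.7%. On chromosome 15, 4 sites between 6.84% and 25.4% from 81524322 to 81525046 were flanked by 2 sites on each side at 95.8% or more. The first 2 of these flanking sites held only 40 and 52 summed reads. With a minimum of 50 reads in every library they were lost, and the cluster mean went from 58.4% to 44.8%.

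**Figure D2:**
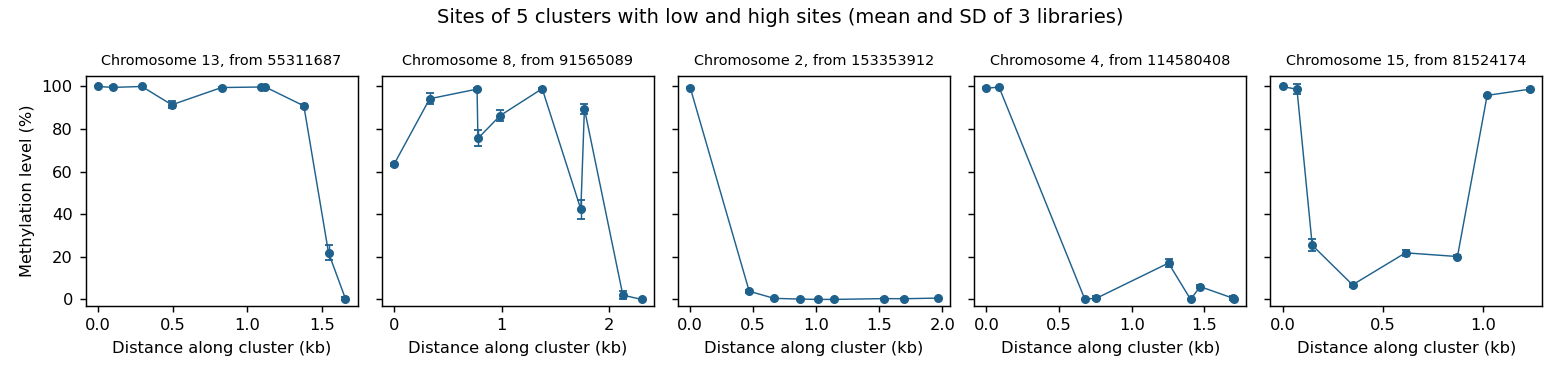
Methylation level (%) of each covered site against its distance along the cluster (kb), for the 5 clusters with a low and a high site that hold the most sites; points are means and error bars SDs of 3 libraries, and lines join adjacent sites. The cluster of chromosome 2 drops from 99.5% to 3.82% between its first and second site, and that of chromosome 15 is high at both ends and between 6.84% and 25.4% in the middle. The first 2 sites of the cluster of chromosome 15 hold only 40 and 52 summed reads.

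The X chromosome differed from every autosome. Of its 474 covered sites, 40.9% ± 1.17 (SD, n = 3) were partial, against 15.4% ± 0.222 of the 23638 autosomal sites and at most 17.2% on any autosome (chromosome 7). Low sites made up 24.7% of X sites and 45.7% of autosomal sites; the autosomes ranged from 41.6% (chromosome 15) to 51.5% (chromosome 16). Among clustered sites, 49.7% ± 1.21 of the 143 on X were partial, against 13.2% ± 0.145 on the autosomes, whose range was 9.09% (chromosome 13) to 16.9% (chromosome 7). Low sites were 18.2% of the clustered sites on X and 63.1% of those on the autosomes, and high sites were 32.2% and 23.7%. Isolated sites were partial in 34.6% ± 1.95 on X and 15.4% ± 0.134 on the autosomes. The high share had no common direction: it was higher on X among clustered sites, but lower over all sites (34.4% against 38.9%) and among isolated sites (44.9% against 57.1%), in both below each of the 19 autosomes.

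The planned comparison joined the partial and high classes. Their share was higher on X by 21.0 percentage points ± 0.607 (SD, n = 3) over all sites, with p = 1.18e-20 by Fisher's exact test over sites. Over clustered sites it was higher by 45.0 points ± 1.45 with an exact p of 1.28e-27. The partial share alone, a comparison chosen after the data were seen, was higher by 25.5 points ± 1.0 (exact p = 1.04e-39) over all sites and by 36.5 points ± 1.33 (exact p = 5.61e-25) over clustered sites. The p-values over sites take nearby sites as independent, so they can be far too small. With 1 value per cluster, 24 of 35 clusters on X and 499 of 1709 on the autosomes were partial by their mean, a difference of 39.4 points (exact p = 2.21e-06). Partial sites were spread along X: in the 9 bins of 20 Mb their share lay between 29.1% (120 to 140 Mb) and 47.8% (40 to 60 Mb). With the adjusted percent, 35.9% of X sites and 14.5% of autosomal sites were partial.

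**Figure D3:**
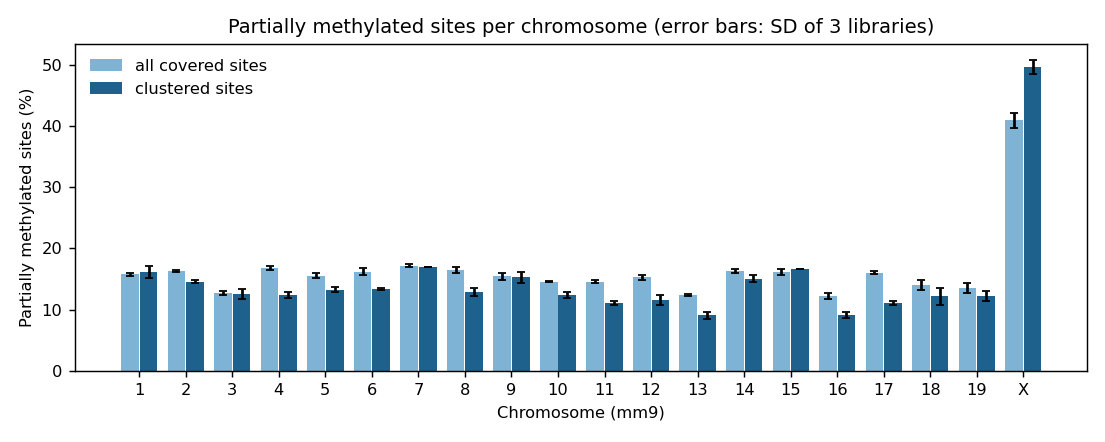
Percent of covered sites (light bars) and of clustered sites (dark bars) that were partially methylated (mean level of 10% to under 70%) on each chromosome, with the SD of the 3 libraries as error bars. X stands at 40.9% and 49.7%, and no autosome passes 17.2%.

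**Figure D4:**
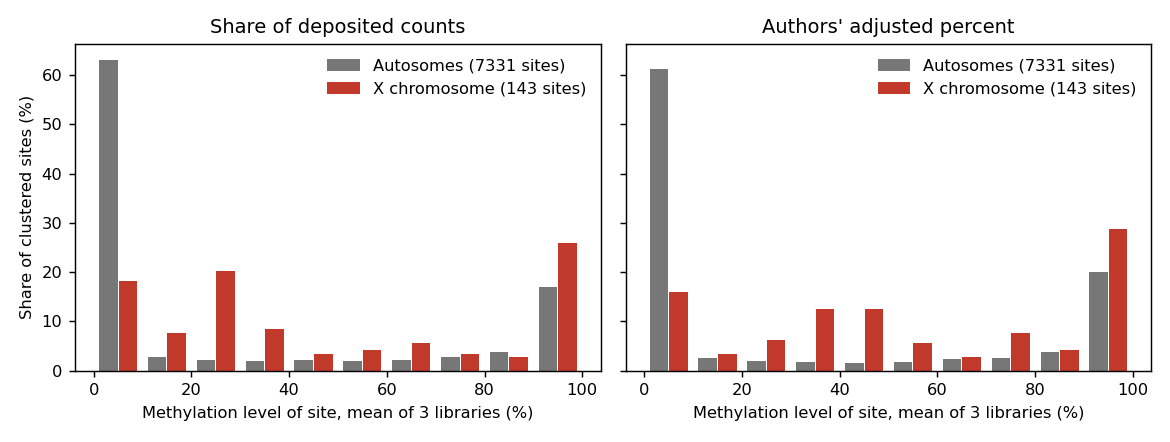
Percent of clustered sites in each band of 10 percentage points of methylation level (mean of 3 libraries), for the 7331 sites of the autosomes (grey) and the 143 of X (red), from the deposited counts (left) and the authors' adjusted percent (right). Autosomal sites gather at both ends, and X sites also between 20% and 40% in the left panel and between 30% and 50% in the right panel.

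Clusters at a middle level throughout were a small share on the autosomes. Every covered site had an adjusted percent of 25 to under 75 in 5 of the 35 X clusters (14.3%) and in 13 of the 1709 autosomal clusters (0.761%), with an exact p of 1.72e-05 by Fisher's test over clusters, a comparison chosen after the data were seen. With the same limits on the deposited counts there were 2 on X and 13 on the autosomes (exact p = 0.0349 by Fisher's test), of which 1 and 7 were among those of the adjusted percent, so the set depends on the adjustment on X and on the autosomes. The X clusters of the adjusted percent started at 49034043, 149203816, 11668208, 39503298 and 147482057, and their adjusted means were 38.8%, 35.3%, 50.9%, 47.3% and 38.0%, against 25.8%, 22.8%, 36.3%, 33.4% and 25.3% from the deposited counts. They held 7803, 3286, 2978, 427 and 252 summed reads, and with a minimum of 50 reads in every library no site of the last 2 was left. Of the autosomal ones, the deepest lay on chromosome 17 from 39985227 to 39985699. Its 4 sites had an adjusted mean of 49.0% ± 0.691 (SD, n = 3), or 35.2% from the deposited counts, over 767908 reads. Whether so many reads come from 1 locus was not tested, so this level may average several genomic copies. The cluster of chromosome 1 from 136605656 to 136606234 had an adjusted mean of 54.2% ± 1.24 (39.2% from the deposited counts) over 7395 reads. By the adjusted percent, that of chromosome 3 from 120965410 to 120966048 was at 53.5% ± 1.26, that of chromosome 5 from 130090225 to 130090987 at 37.0% ± 2.17 and that of chromosome 2 from 151874489 to 151875112 at 62.9% ± 1.98. On chromosome 6, the sites from 6810640 to 6811036 averaged 61.6% ± 0.892.

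Isolated autosomal sites were also compared between windows of 5 Mb. Over 181 windows with at least 10 runs of sites, the means ranged from 24.5% to 95.3% with a median of 63.4%. The lowest were chromosome 14 from 60 to 65 Mb (24.5% ± 2.02, SD, n = 3), chromosome 17 from 70 to 75 Mb (30.7% ± 1.48) and chromosome 3 from 85 to 90 Mb (30.8% ± 1.25). The highest were chromosome 5 from 130 to 135 Mb (95.3% ± 0.655), chromosome 13 from 35 to 40 Mb (91.0% ± 0.577) and chromosome 1 from 70 to 75 Mb (88.4% ± 1.84). The SD between window means was 12.3 percentage points, against 10.3 on average when levels were shuffled among windows (permutation p = 0.00033, one-sided, 100000 shuffles). The call was lost with at least 50 reads per library (permutation p = 0.549) and with spacing limits of 250 bp (p = 0.0805) and 1 kb (p = 0.382). Without replicate 1 the SD was 10.7 (permutation p = 0.0354), against permutation p = 0.00177 and p = 0.00212 without replicates 2 and 3. Coverage was then required only in the libraries kept, so the sites changed too and the shift cannot be credited to replicate 1.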

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

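Of the tests in this part, those of adjusted levels and of reads from other genomic copies were chosen after the result was seen; the others were set before their values were seen, though the excess spread between libraries was already known.

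Reads were also counted at sites that the comparisons leave out. The series table holds 22299 sites with at least 10 summed reads but fewer than 10 in some library. They held 1.5% of the summed reads, with a median of 15 reads per site, and their mean level was 65.4%, with 60.6% of them high, 19.8% partial and 19.5% low. Isolated sites made up 83.9% of them against 24.6% of the covered sites, and isolated sites had a mean pooled level of 69.5% here and 60.8% among the covered sites.

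The tables argue against too few reads as the cause of the partial methylation of X. If too few reads caused it, it would fade at depth, but with at least 50 reads in every library 42.2% of X sites were partial against 18.3% on the highest autosome. With the authors' factors 35.9% of X sites stayed partial against at most 16.6% on an autosome. This cannot decide on under-recovery of methylated reads. The same factor applies to every chromosome of a library, and factors of this size leave most partial sites partial. Reads from other genomic copies cannot be told apart: partial X sites lay at a median log2 depth ratio of -0.35 ± 0.03 (SD, n = 3) to matched autosomal sites, below 0 but above the low (-0.77) and high (-0.63) sites of X itself. No biological explanation was tested, since there is 1 group; X inactivation in a line labelled female and a mixture of cells with different X states are untested hypotheses, and the depth of X itself, at -0.54 to matched autosomal sites and -0.30 without matching on fragment length, leaves the number of X copies open.

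The spread between libraries was 1.37 times counting error over the 3 pairs by the likelihood-ratio chi-square. If it came from library-wide differences in the recovery of methylated reads as large as the authors' factors, entering those factors would bring it towards 1, but it rose to 1.69. The factors may therefore carry differences between libraries that the genomic sites do not share, and the SD of the mean level was 0.327 percentage points with them and 0.170 without. Repeated copies of the same molecule would add spread at deep sites; the ratio of the deepest to the shallowest 25% of sites was 1.12 on average, with 1.19, 1.0 and 1.15 for the 3 pairs, so this cannot be told apart. No biological explanation was tested.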

How the results depend on the processing

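The adjusted percent, the spacing limits, the library factor as an offset, the undivided chi-square, middle-level clusters by the deposited counts, the removal of the 7 deepest sites, other classes for X and every alternative for clustered sites, clusters, windows and depth were chosen after seeing the data; the others were planned. The comparisons of X with the autosomes kept their direction and stayed past the threshold under every alternative run, with a partial share higher on X by 20.8 to 27.4 percentage points over all sites. With minimums of 20 and 50 reads and with 30 pooled reads, the mean level was 40.2%, 38.5% and 45.1%, low sites made up 48.5%, 50.2% and 43.3%, high sites 35.6%, 33.8% and 40.8%, and clustered sites differed from isolated ones by -27.0, -20.5 and -35.0 percentage points. With the adjusted percent these values were 46.5%, 42.8%, 42.3% and -33.5, and partial sites 14.9%. Classes at 20% and 80% gave 48.7% low, 15.4% partial and 35.8% high sites, and a class required in each library gave 43.8%, 13.1% and 37.5%. Clustered minus isolated was -24.4 with a limit of 250 bp, -63.4 with 1 kb and -33.5 on autosomes alone. A limit of 250 bp left 100 clusters with every site high, 413 with every site low and 62 with both; 1 kb gave 492 with both, and a minimum of 50 reads gave 117 with every site high and 160 with both. The SD between 5-Mb windows was 11.2 (permutation p = 0.549) with 50 reads, 9.96 (p = 0.0805) with 250 bp and 6.47 (p = 0.382) with 1 kb. Sites called between libraries numbered 20 without a minimum difference, 2 with a chi-square test in place of Fisher's and 0 with that chi-square divided by the dispersion. Leaving out each replicate gave 0 to 1 such sites (0 without replicate 1, 1 without replicate 2 and 1 without replicate 3), mean levels of 43.4% to 44.8%, low sites of 43.8% to 45.0%, partial sites of 15.6% to 16.0%, high sites of 39.0% to 40.5% and clustered minus isolated of -35.4 to -33.0. For these values coverage was required only in the libraries kept, so the set of sites changed along with the libraries. Without matching on fragment length the log2 depth ratio of chromosome 19 was -0.53, against 0.62 with it, and those of chromosome 15 and X were 0.26 and -0.30, against 0.44 and -0.54. The fall in called sites from 2 to 0 follows the division, by construction; the cause of the other changes was not tested. No paired analysis was possible because there is 1 group. Settings intended for promoters, CpG islands and gene lists were not run. The pairwise test recovered 33% of simulated changes of 20 points between replicates 1 and 2, so changes of that size at single sites can be missed. Part of this loss comes from the call rule and not from depth, since a call needs an observed difference of at least 20 points. The simulated counts held counting error only, without the excess spread between libraries.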

Other observations

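Of the tests in this part, that of site density on chromosome 15 was set before its value was seen, though the depth ratios were known; those on chromosomes 11 and 19 and that of fragment lengths were chosen after the result was seen.

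The deepest reads came from a short stretch of chromosome 17. Of the 7 sites with over 50000 summed reads, 6 lay between positions 39981186 and 39985699, and the 7 sites together took 6.23%, 6.18% and 6.16% of all reads in replicates 1, 2 and 3. Of these 6 deep sites 5 were partial, from 22.3% ± 0.776 (SD, n = 3) at 39985699 to 48.4% ± 0.232 at 39985227. The site at 39983500 was at 0.0084% ± 0.0050 over 157153 reads, while the site at 39983068, over 205382 reads, was at 38.3% ± 0.544. The remaining deep site, at 108873185 of chromosome 11, was at 0.0671% ± 0.0146 over 240822 reads. Whether the reads of these 7 sites come from single loci or from several genomic copies was not tested.

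The other 7 autosomal clusters at a middle level in every site had fewer reads. They lay on chromosome 10 from 61573532 to 61574029 (adjusted mean 65.0% ± 2.40, SD, n = 3), chromosome 16 from 97578164 to 97578518 (57.5% ± 1.47), chromosome 9 from 56644160 to 56644787 (46.3% ± 3.26) and chromosome 3 from 122432564 to 122432926 (38.4% ± 3.55). The remaining ones lay on chromosome 17 from 45509496 to 45510308 (61.7% ± 4.50), chromosome 1 from 74115380 to 74115851 (43.3% ± 0.270) and chromosome 5 from 30890333 to 30890680 (43.8% ± 6.79).

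Matched on fragment lengths and methylation class, the median log2 depth ratio was 0.62 ± 0.02 (SD, n = 3) on chromosome 19 (95% bootstrap interval 0.47 to 0.71), 0.44 ± 0.00355 on chromosome 15 (0.36 to 0.48), 0.25 ± 0.01 on chromosome 11 (0.21 to 0.30) and -0.54 ± 0.00716 on X (-0.63 to -0.43); without matching on length the ratios were -0.53, 0.26, 0.27 and -0.30. On chromosome 19 the matched ratio differed by class, at 0.82 ± 0.01 for low, 0.67 ± 0.04 for partial and 0.39 ± 0.06 for high sites. Fragment lengths as the whole cause are argued against on chromosomes 11 and 15, whose excess stood before and after matching, and cannot be told apart on chromosome 19, where the excess appears only with matching. Against site density, the matched ratios of chromosomes 15 and 19 lay 2.33 and 3.74 residual SDs above the line through the other 18 autosomes. Both were known to have the highest matched ratios, so these distances alone cannot decide on site density. Chromosomes 4, 5, 11 and 17 have more listed sites per Mb than either, yet lower matched ratios (-0.15, 0.05, 0.25 and -0.0023). This comparison, made after the values were seen, argues against site density as the whole cause on chromosomes 15 and 19. On chromosome 11 density cannot be told apart, since the distance was 0.124 residual SDs from a line that includes chromosomes 15 and 19 and 2.84 from a line through the 16 autosomes without them. The matched ratios of those 16 autosomes ranged from -0.19 (chromosome 16) to 0.18 (chromosome 6). No biological explanation was tested, and copy number was not measured on any chromosome. Extra copies of chromosome 15 in this line are an untested hypothesis, since no DNA of a normal mouse was compared.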
